A study of Mus musculus with 4 samples.

How the data were processed

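Single-cell RNA libraries were analysed from cultures of bone-marrow-derived macrophages, the adherent cells that grow from mouse marrow in macrophage colony-stimulating factor (M-CSF). Per the labels' protocols, marrow came from male mice aged 7 to 8 weeks, wild type or Notch2 mutant, that were sex-matched littermates. Cells were expanded with M-CSF, plated on collagen on day 3, and kept for 3 days either in 30 ng/ml of M-CSF or with RANKL at 10 ng/ml added, the cytokine that turns macrophage precursors into osteoclasts. They were lifted with collagenase and made into 10x Genomics libraries. Each of the 4 combinations of genotype and treatment had 1 library. The labels name the genotype only as Notch2 mutant, so the kind of mutation is not stated here. The bulk RNA sequencing that the design text mentions was not analysed here.

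The deposited values were raw UMI counts per gene and barcode, in filtered matrices that the authors made with Cell Ranger 7.0.1 against mm10, per the submitters' processing notes and the file headers. The annotation release and the aligner settings were not given in the sources used here. Each library held at least 500 UMIs in every barcode. The matrices list 32285 genes, of which 32158 were matched by Ensembl identifier to GENCODE release M21 (GRCm38), which supplied the coordinates. Each library came with a second copy of its matrix whose counts were identical line by line, and 1 copy was used.

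From these counts, barcodes were kept with at least 500 detected genes and at most 15% of UMIs from mitochondrially encoded genes. Scrublet, run per library through Scanpy 1.11.5 at its automatic threshold, then removed 39, 14, 42 and 4 barcodes as doublets in the wild type M-CSF, mutant M-CSF, wild type RANKL and mutant RANKL libraries. It marked 4 of 5776 barcodes in the mutant RANKL library, 0.0693%, so it did not work there, and that library has in effect had no doublet removal. Kept cells numbered 3908, 2672, 3996 and 5772 in the same order, which was 75.8%, 81.4%, 70.1% and 74.5% of barcodes. In those libraries, 912, 331, 1079 and 1230 barcodes had under 500 genes, and 328, 320, 630 and 814 exceeded the mitochondrial limit. Cells were not treated as replicates.

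UMIs were summed over the kept cells of a library and scaled to CPM, counts per 1000000 of the library's kept total. Genes with at least 20 CPM in the higher library of a contrast entered it, and those at least 2-fold apart were counted. With 1 library per group no test was made, no p-value is given, and no difference has a replicate check. Ratios carry exact conditional binomial 95% intervals, CPM exact Poisson intervals and shares of cells exact Clopper-Pearson intervals, all covering counting error only. A library at 0 UMIs was set to 3 UMIs for a ratio. That ratio is called a lower bound below, although the lower limit of its 95% interval is smaller still. The difference in RANKL response was the log2 ratio in the mutant minus that in the wild type.

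The genes named were fixed by rule. For each contrast they are the 12 highest and 12 lowest log2 ratios among genes at least 2-fold apart that had the same direction when each cell was weighted equally, leaving out predicted gene models. For the difference in response they are the 6 highest and 6 lowest. Some genes that these rules pick are not reported here, though the counts include them. Members of the gene lists are named as examples. Other genes named within macrophage-like or osteoclast-like cells, such as Cd55 and Tgfbi, were chosen after their values were seen, as were genes marked so elsewhere. Hist1h2ap, Bcl2a1b, Wfdc17 and Ctla2b have near-identical copies or close relatives that counting can split, so their values are uncertain.

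There were 25 gene lists, of which 23 had enough measured members for a median: osteoclast genes, V-ATPase subunits, RANKL and AP-1 signalling, repressors of osteoclastogenesis, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, the tricarboxylic acid cycle, glycolysis, mitochondrial biogenesis, iron and heme handling, cholesterol synthesis and uptake, macrophage genes, MHC class II, interferon response, inflammatory cytokines and chemokines, matrix metalloproteinases and inhibitors, S phase, G2 and M phase, dissociation and heat shock response, hypoxia, unfolded protein response, cell fusion and cytoskeleton, and ribosomal proteins. The Notch receptor and ligand list and the Notch target list had too few. Members needed at least 5 CPM in either library. A list's median log2 ratio is given with the central 95% range of 2000 Poisson resamples of the counts, and with its percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries only.

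Cells of the 4 libraries were clustered together without batch integration: counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours in a shared-neighbour graph (scikit-learn 1.9.0) and Leiden resolution 0.5 (leidenalg 0.10.2, python-igraph 0.11.9), which gave 17 clusters. A cluster was named after a cell type by a fixed list of markers enriched in it, except for macrophages. Macrophage-like was the default name where most macrophage markers were widely detected and no other type's marker was among the 10 leading genes. The macrophage-like clusters had 0 macrophage markers among these 10. The rule for scoring markers was set after the clusters were seen, and 3 clusters stayed unnamed under it. A clause added after seeing the data leaves a low-UMI cluster unnamed where a predicted gene model leads it. That clause kept cluster 12, described below, from being called osteoclast-like. To compare shares of cells with an Atp6v0d2 UMI, each cell was thinned to 3000 UMIs and shallower cells were left out. The ratio and interval code was tested on simulated counts drawn from the real libraries with 200 genes altered. In each of the 4 contrasts it called 99% to 100% of genes altered by a log2 of 1.5 and 0% of those altered by 0.5. It called 0 unaltered genes, and its intervals covered 95.1% to 95.4% of the true ratios. The draws were Poisson, as the intervals assume, and the median shift of unaltered genes was taken off first. Coverage near 95% was thus built in and does not extend to UMIs clumped in few cells.

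The groups, the contrasts, the cell filters, the gene lists, the markers and the first set of alternatives were set before the data were examined. Alternatives chosen at that stage were all barcodes, a stricter filter of 1000 genes and 10% mitochondrial UMIs, Scrublet calls kept, edgeR 4.0.16 TMM factors in R 4.3.3, the mean of per-cell CPM, other cell types or cycling cells left out, other expression minimums (50 CPM, or 10 UMIs over both libraries, or 20 CPM for list members), other thinned depths (1500 or 5000 UMIs, or none) and other clusterings (resolution 1.0, 1000 variable genes, and 2 gene exclusions). Added after seeing the data were a mitochondrial limit of 30%, removal at a Scrublet score of 0.25, removal of the low-UMI clusters 2 and 12, removal of osteoclast-like cells, alone or with cluster 12, and, within macrophage-like cells, subtraction of free osteoclast RNA. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.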

Results

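Bone-marrow-derived macrophages from wild type and Notch2 mutant mice were profiled by single-cell RNA sequencing after 3 days with M-CSF alone or with M-CSF and RANKL, in 1 library per combination. NOTCH2 is a cell surface receptor whose cleaved intracellular part acts in transcription. The series title names osteoclast maturation, metabolism and the transcriptome during osteoclast formation as its subject. The wild type M-CSF, mutant M-CSF, wild type RANKL and mutant RANKL libraries held 5156, 3283, 5697 and 7750 barcodes with 52101883, 23503854, 46228185 and 56935502 UMIs. After filtering, 3908, 2672, 3996 and 5772 cells remained, with medians of 12315, 8004, 9555 and 7879 UMIs per cell and kept totals of 49249164, 22296566, 41413322 and 51682516 UMIs. The median depth of kept cells was thus lower in the mutant library under both treatments. With RANKL the macrophage-like cells described below had nearly equal medians, 9662 UMIs in the mutant and 9715 UMIs in the wild type, and the mutant library held more cells of a low-UMI cluster. With M-CSF, macrophage-like cells had medians of 8211 and 13253 UMIs in the same order. No difference below has a replicate check. All intervals are at 95% and cover counting error only.

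The mutated gene was read first as a check of the labels. Notch2 (ENSMUSG00000027878, chromosome 3, 98013527 to 98150361, plus strand, mm10) stood at 223 CPM (219 to 227) in wild type and 220 CPM (214 to 226) in mutant cells with M-CSF. With RANKL it stood at 217 CPM (212 to 221) in wild type and 220 CPM (216 to 224) in mutant cells. A count of 3' transcript ends need not differ under a mutation that leaves the 3' end intact, and the kind of mutation is not stated in the labels, so these levels neither check nor contradict the genotype. Notch1 was at 48.7 and 51.9 CPM in the wild type and mutant libraries with M-CSF, and at 31.5 CPM in both with RANKL. No other receptor or ligand of the Notch list reached 5 CPM. Of the Notch targets, Hes1, a transcriptional repressor, lay between 0.179 and 0.522 CPM in the 4 libraries, too few UMIs to compare. Myc stood at 3.25, 3.18, 5.87 and 7.14 CPM, and Ccnd1, which encodes cyclin D1, at 8.24, 8.79, 10.4 and 11.9 CPM, in the order wild type M-CSF, mutant M-CSF, wild type RANKL and mutant RANKL.

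The first comparison asked how RANKL altered the wild type cultures. Genes of the osteoclast programme were among those higher with RANKL by the widest margins. Acp5, which encodes tartrate-resistant acid phosphatase (chromosome 9, 22126727 to 22135711), stood at 878 CPM against 10.6 CPM, a log2 ratio of 6.37 (6.25 to 6.5). Ctsk, the collagen-degrading protease cathepsin K (chromosome 3, 95499256 to 95509362), stood at 827.5 against 5.44 CPM, a log2 ratio of 7.25 (7.08 to 7.43). Mmp9, a gelatinase (chromosome 2, 164940780 to 164955850), was higher by 4.50 (4.43 to 4.58), and Atp6v0d2, a proton pump subunit that takes part in cell fusion (chromosome 4, 19876841 to 19922605), by 2.04 (1.959 to 2.117).

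Of 6454 genes in the wild type contrast, 80 were at least 2-fold higher with RANKL and 22 at least 2-fold lower. The genes with the highest ratios included Mt3, a metallothionein, which had 0 UMIs with M-CSF. With these set to 3 UMIs it was 1305-fold higher, a log2 ratio of 10.35 with a lower limit of 10.05. Oscar, an osteoclast-associated immunoreceptor, had a log2 ratio of 9.72 (7.86 to 12.76) resting on 2 UMIs with M-CSF. Slc9b2, a sodium-proton exchanger, Dcstamp, a membrane protein needed for fusion, and Car2, carbonic anhydrase 2, were higher by 9.35, 8.92 and 7.37. Scin, an actin-severing protein, and Akap6, an anchor for protein kinase A, were higher by 5.18 and 5.04. Ppbp, a platelet chemokine, and Igkc, the immunoglobulin kappa constant region, completed this set at 6.82 and 4.96, but 97.8% and 96.7% of their UMIs with RANKL lay in 5 cells. Among the lowest, Prg2, an eosinophil granule protein, stood at -6.31, with 99.5% of its M-CSF UMIs in 5 cells. Cd5l, a secreted scavenger-receptor protein of macrophages, was lower by a log2 ratio of -2.89 (-2.98 to -2.80), at 24.8 against 183 CPM. Mthfs, a folate enzyme, Bcl2a1b, a survival factor, and Fcgr2b, the inhibitory IgG receptor, stood at -1.88, -1.73 and -1.42. Secreted products were among the rest, with Wfdc17 at -1.47, the acute phase protein Saa3 at -1.38, the chemokine Ccl6 at -1.37 and Fgl2 at -1.21. Lhfpl2 stood at -1.34, the membrane metalloproteinase Adam8 at -1.28 and the stress gene Gadd45a at -1.27.

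In the Notch2 mutant cultures, too, genes of the osteoclast programme were higher with RANKL. Acp5 stood at 1277 against 14.0 CPM, a log2 ratio of 6.51 (6.35 to 6.68), and Ctsk at 1218 against 5.70 CPM, a ratio of 7.74 (7.49 to 8.00). Mmp9 was higher by 4.77 (4.67 to 4.88) and Atp6v0d2 by 2.34 (2.23 to 2.44). Of 6459 genes, 116 were at least 2-fold higher and 32 at least 2-fold lower. Mt3, with 0 UMIs set to 3, was 1028-fold higher, a log2 ratio of 10.005 with a lower limit of 9.707. Oscar, Car2, Slc9b2 and Ocstamp, a partner of Dcstamp in fusion, were higher by 9.96, 9.55, 8.66 and 8.14. Dcstamp and Mst1r, a receptor tyrosine kinase, had 0 UMIs with M-CSF in the mutant. With these set to 3 UMIs, their log2 ratios were 8.18 and 7.35, with lower limits of 7.88 and 7.05. Akap6 and Scin were higher by 6.77 and 5.58. Cd5l was lower by a log2 ratio of -2.97 (-3.06 to -2.88). Pdzk1ip1 and Bcl2a1b stood at -1.88 and -1.86, Mthfs at -1.77, Wfdc17 at -1.59 and Ccl6 at -1.56. Lhfpl2 at -1.51, Fcgr2b at -1.36, Ctla2b at -1.28, Gadd45a at -1.27, Saa3 at -1.26 and the cytokine Tnf at -1.26 made up the remainder.

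**Figure D1:**
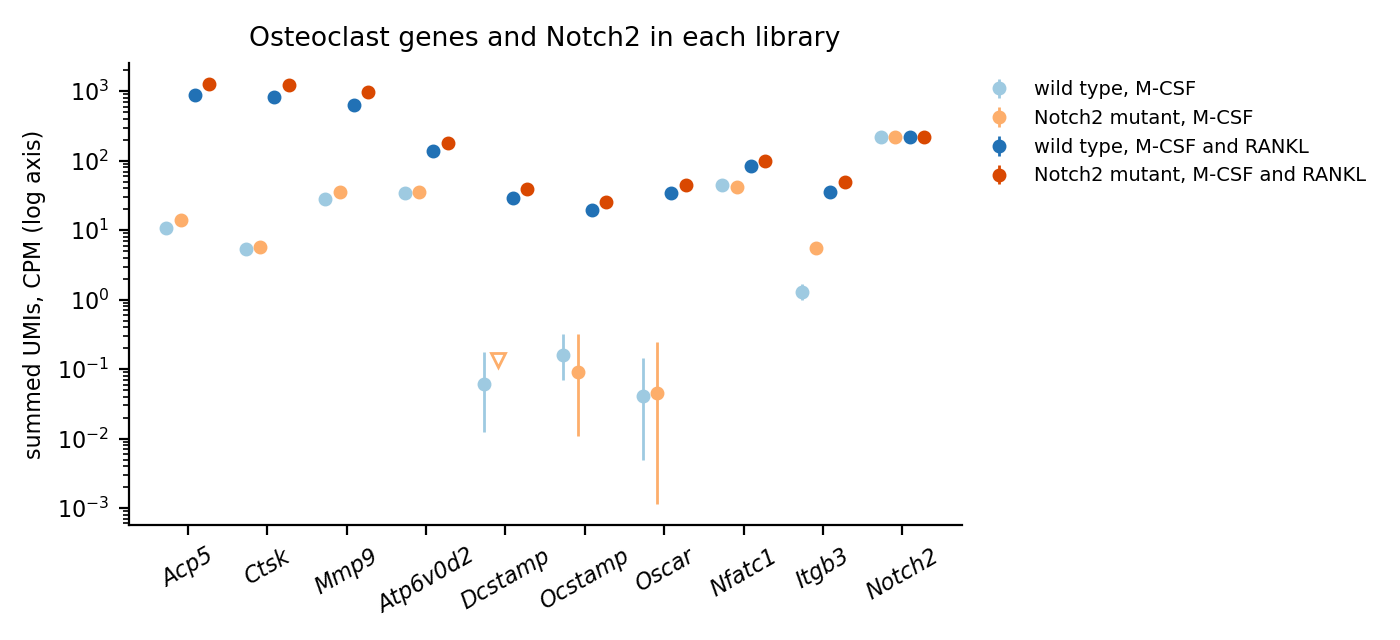
Summed UMIs of 9 osteoclast genes and Notch2 in each library, in CPM on a log axis, with points for the 4 libraries, bars for exact Poisson intervals of counting error and an open triangle for Dcstamp at the limit of 3 UMIs in the mutant M-CSF library. Acp5, Ctsk and Mmp9 lie at 640.5 CPM or above in both RANKL libraries and at or below 35.3 CPM in both M-CSF libraries, while Notch2 lies between 217 and 223 CPM in all 4.

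The RANKL responses of the genotypes share no library, so they can be set side by side. Among 6368 genes measured in both, 71 were at least 2-fold higher in both and 19 at least 2-fold lower in both, with 0 in opposite directions. Lists of 75 and 99 higher genes drawn independently would share 1.17. Across genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.951 and a Spearman rho of 0.846.

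**Figure D2:**
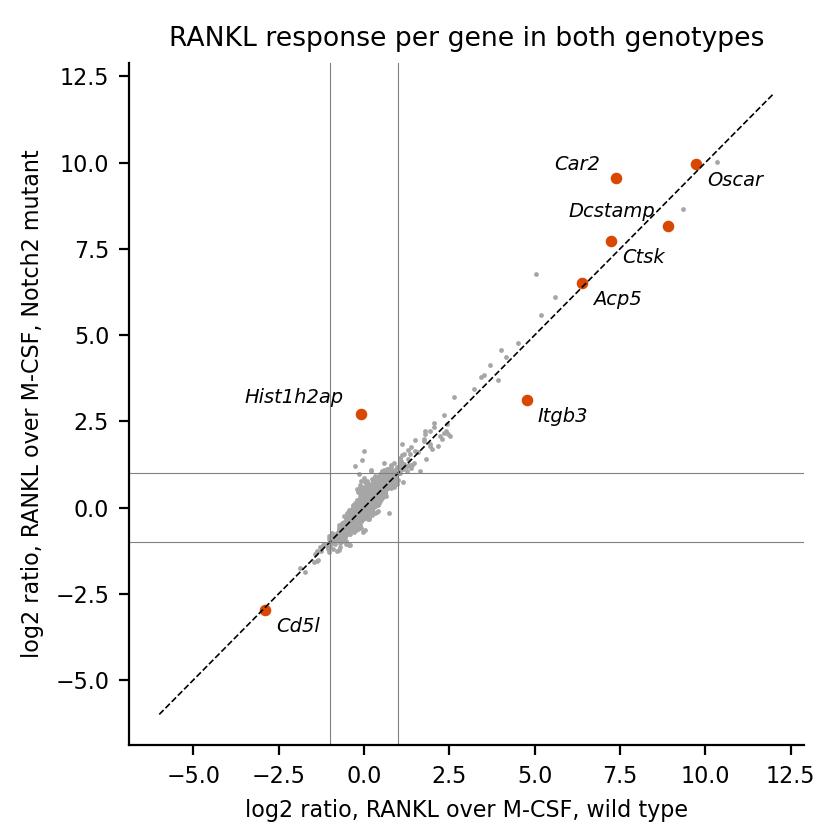
Log2 ratio of RANKL over M-CSF for each of 6368 genes, wild type on the horizontal and Notch2 mutant on the vertical axis, with a dashed line of equality and grey lines at 2-fold. Points follow the line of equality (r of 0.951 across genes), and a few, such as Mt3, are lower bounds because they had 0 UMIs with M-CSF.

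By gene list, 22 of the 24 measured osteoclast genes had intervals above a ratio of 1 in each genotype. The list's median log2 ratio was 3.12 (2.84 to 3.38) in wild type and 3.12 (2.89 to 3.38) in mutant cells, above all random lists. Nfatc1, the transcription factor that drives the programme, was higher by 0.89 and 1.28, and Ckb, a brain-type creatine kinase, by 2.06 and 2.44. Clcn7, a lysosomal chloride transporter, stood at -0.040 and 0.057, and Plekhm1 at -0.22 and -0.12. With the osteoclast-like cells described below left out, an alternative added after seeing the data, the list's medians were 0.044 and 0.10. With each cell weighted equally they were 1.961 and 1.854, with the stricter cell filter 1.965 and 2.193, and over members with at least 20 CPM 2.047 and 2.443.

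Genes of oxidative phosphorylation and the tricarboxylic acid cycle were higher with RANKL by smaller ratios, while glycolysis and mitochondrial biogenesis went both ways. All 76 nuclear genes of oxidative phosphorylation had intervals above a ratio of 1 in both genotypes, with medians of 0.38 (0.36 to 0.39) in wild type and 0.55 (0.53 to 0.58) in mutant cells. Examples are Ndufa4 (0.57 and 0.77), Cox5a (0.57 and 0.62) and Cycs, cytochrome c (0.63 and 0.97). The tricarboxylic acid cycle had medians of 0.31 and 0.44, with Idh3a, a subunit of isocitrate dehydrogenase, at 0.80 and 1.23. Glycolysis stood at 0.19 and 0.12, with 10 and 11 of 17 genes having intervals above a ratio of 1 and 3 below in each genotype, the mitochondrially encoded genes at 0.22 and 0.19 (-0.18 in mutant cells when cells were weighted equally), and mitochondrial biogenesis at 0.087 and 0.086, with 6 and 4 of 12 genes above and 2 and 1 below, although Ppargc1b, a coactivator on that list, was higher by 1.94 and 2.21. The 15 V-ATPase subunits, which acidify lysosomes and the resorption pit, had medians of 0.33 and 0.38. Without osteoclast-like cells, oxidative phosphorylation stood at 0.18 and 0.26, the tricarboxylic acid cycle at 0.13 and 0.17 and the V-ATPase at 0.042 and 0.066.

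Most macrophage genes were lower with RANKL in both genotypes, while inflammatory genes went both ways. Of 20 macrophage genes, 17 in wild type and 16 in mutant cells had intervals below a ratio of 1, and the medians were -0.28 and -0.37. The share of UMIs from macrophage-like cells, described below, moved with this list, from 67.6% with M-CSF to 55.1% with RANKL in wild type and from 72.6% to 49.1% in mutant cells, and within these cells the medians were -0.16 (-0.18 to -0.090) and -0.15 (-0.18 to -0.11). Csf1r, the M-CSF receptor, stood at -0.39 in both, Apoe at -0.73 and -0.96, and C1qa, a complement component, at 0.50 and 0.48 in the other direction. Inflammatory cytokines and chemokines had medians of -0.19 and -0.57, with Il1a at -2.12 and -2.55. Of these 20 genes, 11 in wild type and 13 in mutant cells had intervals below a ratio of 1, and 7 and 5 above. Iron and heme handling stood at -0.31 and -0.44, with the iron exporter Slc40a1 at -0.89 and -0.92, and cholesterol synthesis and uptake at -0.11 and -0.084. Matrix metalloproteinases and inhibitors stood at -0.033 and -0.24 as a list, although Mmp9 is a member, and the MHC class II list at 0.31 and 0.38. Dendritic-like cells, whose leading genes include members of the last list, gave 4.12% of wild type UMIs with M-CSF and 6.01% with RANKL, and 4.11% and 5.42% of mutant UMIs. Within them the MHC class II medians were -0.23 and -0.037, and within macrophage-like cells 0.43 and 1.97. Proliferation genes were higher, with medians of 0.58 and 0.58 for G2 and M phase and of 0.32 and 0.45 for S phase. The share of UMIs from dividing cells moved with these lists, from 8.74% with M-CSF to 12.4% with RANKL in wild type and from 7.395% to 10.91% in mutant cells. The remaining lists had medians near 0 in wild type and mutant cells: RANKL and AP-1 signalling 0.047 and 0.053, where Nfkb2 was higher by 1.18 and 1.28; repressors of osteoclastogenesis 0.027 and -0.10; interferon response -0.038 and 0.047; heat shock and dissociation response 0.063 and -0.046; hypoxia 0.029 and 0.025. Cell fusion and cytoskeleton stood at 0.23 and 0.29, the unfolded protein response at 0.14 and 0.12 and ribosomal proteins at 0.12 and 0.10.

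The comparison of genotypes with M-CSF asked whether the mutant macrophages differed before RANKL. Few genes did. Of 6222 genes, 0 were at least 2-fold higher in the mutant and 3 at least 2-fold lower. These were Prg2 (0 UMIs in the mutant), Hist1h2ap, a histone H2A gene, at 26.8 against 60.4 CPM, and Mpo, the myeloperoxidase of granulocyte precursors, at 28.2 against 59.3 CPM. Of the lists, S phase had a median of -0.20 (-0.28 to -0.14), G2 and M phase -0.16 (-0.22 to -0.12) and the interferon response -0.10 (-0.18 to -0.058). Dividing cells gave 8.74% of wild type and 7.395% of mutant UMIs, a share that moved with the cell cycle lists. Inflammatory cytokines and chemokines stood at 0.13 (0.085 to 0.18), heat shock and dissociation response at 0.13 (0.12 to 0.19), iron and heme handling at 0.11 and macrophage genes at 0.10 (0.075 to 0.13). The share of UMIs from macrophage-like cells moved with the last list, at 67.6% in wild type and 72.6% in mutant cells. Oxidative phosphorylation stood at -0.047 (-0.060 to -0.027), with 32 of 76 genes having intervals below a ratio of 1 and 6 above. Osteoclast genes had a median of 0.051 (-0.003 to 0.096) over 15 measured members. The other lists lay between -0.06 and 0.12. Mpo is a gene of granulocyte precursors and Hist1h2ap of dividing cells, but with RANKL, given below, Hist1h2ap did not follow the share of dividing cells. With the named classes other than macrophages, osteoclasts, monocytes and dividing cells left out, and the unnamed clusters kept, 1 gene was at least 2-fold lower with M-CSF.

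With RANKL, the question was whether osteoclast formation differed between genotypes. Osteoclast genes were higher in the mutant library by a modest ratio that 21 of 24 members shared. Their median log2 ratio was 0.35 (0.29 to 0.38), above all random lists. Ctsk was higher by 0.56 (0.54 to 0.58), Acp5 by 0.54 (0.52 to 0.56), Mmp9 by 0.59 (0.57 to 0.61), Ckb by 0.63 (0.60 to 0.65) and Atp6v0d2 by 0.35 (0.30 to 0.39). Nfatc1 was higher by 0.26 (0.20 to 0.32), while Calcr, the calcitonin receptor, stood at 14.0 against 14.1 CPM, within counting error. With each cell weighted equally the list's median was 0.13, without osteoclast-like cells 0.12, and with all barcodes 0.24.

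Of 6438 genes, 4 were at least 2-fold higher in the mutant RANKL library and 3 at least 2-fold lower. The higher ones included Hist1h2ap (176.5 against 57.3 CPM, a log2 ratio of 1.62) and the predicted genes Gm10076 (1.37) and Gm48099 (1.05), named after their values were seen. The lower ones were Ppbp (-3.01), Igkc (-2.35) and Csmd1 (-1.98), each with at least 96.7% of its wild type UMIs in 5 cells. Oxidative phosphorylation had a median of 0.11 (0.092 to 0.12), with 60 of 76 genes having intervals above a ratio of 1 and 0 below. The V-ATPase stood at 0.099 (0.083 to 0.12), the tricarboxylic acid cycle at 0.070 (0.047 to 0.11) and MHC class II at 0.23 (0.19 to 0.25). Lower in the mutant were G2 and M phase at -0.25 (-0.30 to -0.20), with 18 of 21 genes having intervals below a ratio of 1, S phase at -0.14 (-0.17 to -0.066) and the interferon response at -0.090 (-0.15 to -0.052). Dividing cells gave 12.4% of wild type and 10.91% of mutant UMIs, a share that moved with the cell cycle lists but not with Hist1h2ap. Glycolysis stood at -0.020 (-0.048 to 0.025) and macrophage genes at 0.027 (-0.007 to 0.036). Without osteoclast-like cells, oxidative phosphorylation stood at 0.009 and the tricarboxylic acid cycle at -0.002, which turned its direction, and with the unnamed cluster 12 left out too they stood at -0.005 and -0.015.

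**Figure D3:**
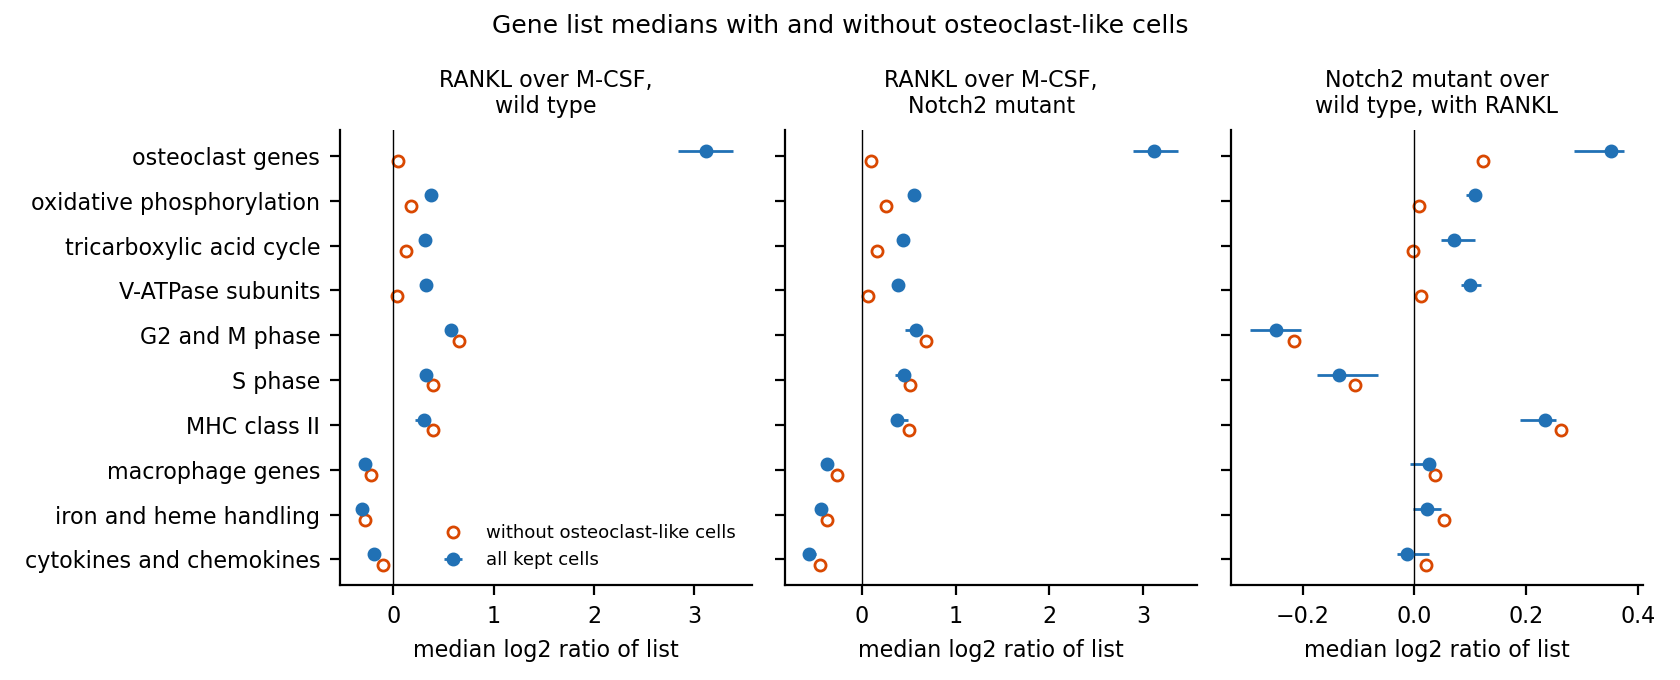
Median log2 ratio of 10 gene lists in RANKL over M-CSF in each genotype and in mutant over wild type with RANKL, the last on its own horizontal scale. Filled points with counting intervals are all kept cells and open points leave out osteoclast-like cells, where the osteoclast list goes from 3.12 to 0.044 in wild type and from 3.12 to 0.10 in mutant cells.

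The difference in RANKL response, mutant minus wild type, was above 0 for 18 of 24 osteoclast genes, with a median of 0.20, and for 69 of 76 oxidative phosphorylation genes, with a median of 0.15. It was below 0 for 17 of 20 inflammatory cytokines and chemokines, with a median of -0.27, and for 14 of 14 heat shock and dissociation genes, with a median of -0.16. With 1 library in each arm this difference was not tested. With each cell weighted equally the 4 medians were 0.004, 0.094, -0.078 and -0.11, with 12, 62, 7 and 5 genes above and 11, 14, 14 and 9 below 0. Without osteoclast-like cells the osteoclast and oxidative phosphorylation medians were 0.089 and 0.024, with 45 oxidative phosphorylation genes above and 31 below 0. Without dividing cells the osteoclast median was 0.12. Only 8 of 6368 genes differed by at least 1 on the log2 scale. The genes with the highest differences included Prg2 (11.24, with 0 UMIs set to 3, interval 8.28 to 14.2), Hist1h2ap (2.79), Car2 (2.17), Akap6 (1.74) and Mpo (1.48). The lowest were Ppbp (-4.57), Csmd1 (-3.45), Igkc (-2.92), the integrin subunit Itgb3 (-1.65) and the kinase Prkca (-0.89). Dcstamp, at -0.74 (-4.01 to 2.53), had 0 UMIs in the mutant M-CSF library, so its difference is a lower bound without a rank. The value for Car2 rests on 2 UMIs in the mutant M-CSF library, and its interval of 0.035 to 4.31 nearly reaches 0. That for Akap6 (0.70 to 2.77) rests on 9 mutant and 46 wild type UMIs with M-CSF, 88.9% and 63.0% of them in 5 cells, and 95.8% of the Prg2 UMIs in the mutant RANKL library lay in 5 cells. Ppbp had a difference of 0.44 when cells were weighted equally, and 88.0% of the 125 Itgb3 UMIs in the mutant M-CSF library lay in 5 cells.

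Clustering separated osteoclast-like cells from macrophage-like, monocyte-like, dividing, dendritic-like and neutrophil-like cells. The osteoclast-like cluster held 93 of 3996 cells of the wild type RANKL library, 2.33% (1.88 to 2.84), and 152 of 5772 cells of the mutant RANKL library, 2.63% (2.24 to 3.08). It held 0 cells of either M-CSF library, which allows shares of up to 0.09435% in wild type and 0.138% in mutant cells. Since the genes that define this cluster differ with RANKL, these sizes are values, not a comparison of treatments. Osteoclast-like cells had medians of 30212 and 31311 UMIs and 10.98% and 10.68% mitochondrial UMIs, and contributed 6.43% of wild type and 9.23% of mutant UMIs. With the low-UMI clusters left out the shares of cells were 2.64% and 3.72%, among all barcodes 2.83% and 2.77%, and with the stricter filter 1.38% and 1.89%. The shares of UMIs were then 8.88% and 11.11% among all barcodes and 2.68% and 4.51% with the stricter filter. Among all barcodes the class also took in a cluster of 57 barcodes with a median of 8573 UMIs. Calcr was the only osteoclast marker among the 10 leading genes of that cluster.

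Macrophage-like cells made up 60.7% and 71.1% of the wild type and mutant M-CSF libraries and 55.5% and 43.0% of the wild type and mutant RANKL libraries. They lay chiefly in different clusters by treatment: clusters 1 and 5 held 32.3% and 25.5% of wild type M-CSF cells, and clusters 3 and 4 held 24.9% and 25.1% of wild type RANKL cells. In the same order of libraries, monocyte-like cells made up 9.65%, 7.78%, 8.96% and 7.21%, and dividing cells 5.35%, 4.57%, 7.06% and 5.27%. Dendritic-like cells made up 4.04%, 4.57%, 5.76% and 4.64%, neutrophil-like cells 5.89%, 5.50%, 5.48% and 4.89%, and B-like cells 0.179%, 0.299%, 0.425% and 0.416%. The split between dividing and neutrophil-like cells depended on the clustering: with 1000 variable genes dividing cells made up 0.358%, 0.823%, 1.85% and 1.68% and neutrophil-like cells 11.2%, 9.99%, 12.5% and 10.2%. Stromal-like cells numbered 3, 2, 5 and 8. No cluster met the naming rule for T or NK cells, mast cells, eosinophils, osteoblasts, endothelial, erythroid or megakaryocytic cells. Unnamed clusters held 14.1%, 6.14%, 14.4% and 31.8% of cells. Among them, cluster 2, with a median of 1054 UMIs per cell, held 11.7%, 3.33%, 10.1% and 26.0%, which takes from the shares of other classes most in the mutant RANKL library. Cluster 12, at 1627 UMIs and with Ctsk, Acp5, Dcstamp and Mt3 among its 10 leading genes, held 0.512%, 0.786%, 1.70% and 3.24%. It had Acp5 at 1560 and 2277 CPM in the wild type and mutant RANKL libraries and at 0 UMIs with M-CSF, so osteoclast-derived barcodes may lie outside the osteoclast-like class. Cluster 12 would have been called osteoclast-like without the naming clause for low-UMI clusters. The osteoclast-like cluster and cluster 12 together held 4.03% and 5.87% of cells and 6.63% and 10.29% of UMIs of the wild type and mutant RANKL libraries. With the osteoclast-like cluster and cluster 12 left out, an alternative added after seeing the data, the osteoclast list stood at 0.013 and 0.087 for RANKL in wild type and mutant cells and at 0.12 for genotype with RANKL. Cluster 10, led by Mmp12 and Lpl, held 1.92%, 2.02%, 2.63% and 2.53%.

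**Figure D4:**
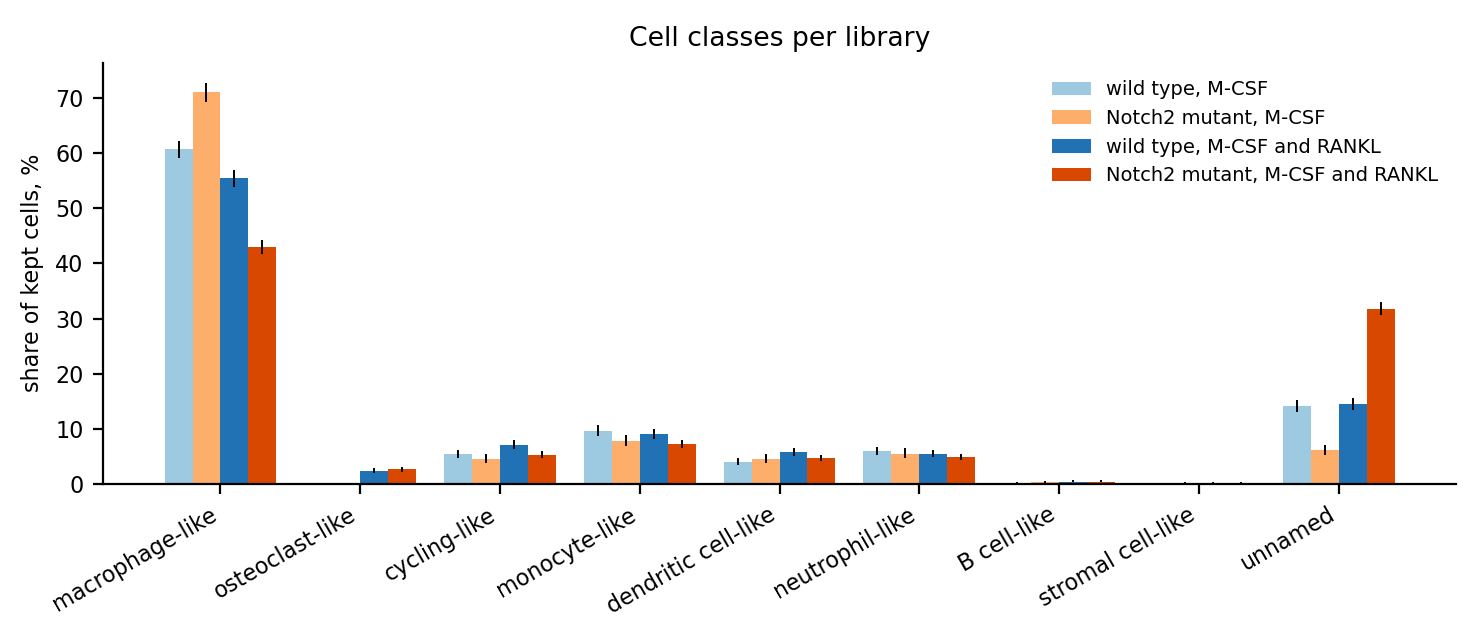
Share of kept cells in each class, in percent, as bars from 0 for the 4 libraries with exact binomial intervals. The osteoclast-like class appears in the RANKL libraries only, at 2.33% and 2.63%, and the unnamed clusters reach 31.8% of the mutant RANKL library.

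Within the RANKL libraries, osteoclast-like cells were set against macrophage-like cells of the same library. Every measured nuclear gene of oxidative phosphorylation was higher in the osteoclast-like cells: the 76 genes had a median log2 ratio of 2.04 (2.01 to 2.08) in wild type and 2.16 (2.13 to 2.19) in mutant cells, with 76 and 75 of them at least 2-fold higher. The tricarboxylic acid cycle stood at 1.83 and 1.94, with Idh3a at 3.79 and 3.97, the V-ATPase at 1.942 and 2.001, and glycolysis at 0.84 and 0.97. Mitochondrially encoded genes stood at 0.95 and 0.87, ribosomal proteins at 0.91 and 0.87 and fusion genes at 0.90 and 0.89, of which 7 and 4 of 22 were at least 2-fold lower. Ppargc1b was higher by 4.38 and 4.2. Lower in osteoclast-like cells were macrophage genes (-5.34 and -3.86), inflammatory cytokines and chemokines (-4.60 and -3.80), interferon response (-3.96 and -3.11), and repressors of osteoclastogenesis (-1.96 and -1.85), among them Irf8 (-5.55 and -3.90). Of 15 repressors, 9 in wild type and 8 in mutant cells were at least 2-fold lower, and 4 and 3 at least 2-fold higher, such as Zeb1 (3.05 and 3.28), Bach2 (2.77 and 2.66) and Nfkbia (1.77 and 1.60). Notch2 was lower, at 32.7 against 248 CPM in wild type and 42.8 against 276 CPM in mutant cells, log2 ratios of -2.93 (-3.25 to -2.62) and -2.69 (-2.90 to -2.49). The osteoclast list stood at 6.19 and 6.13, which follows from how the cluster was named.

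**Figure D5:**
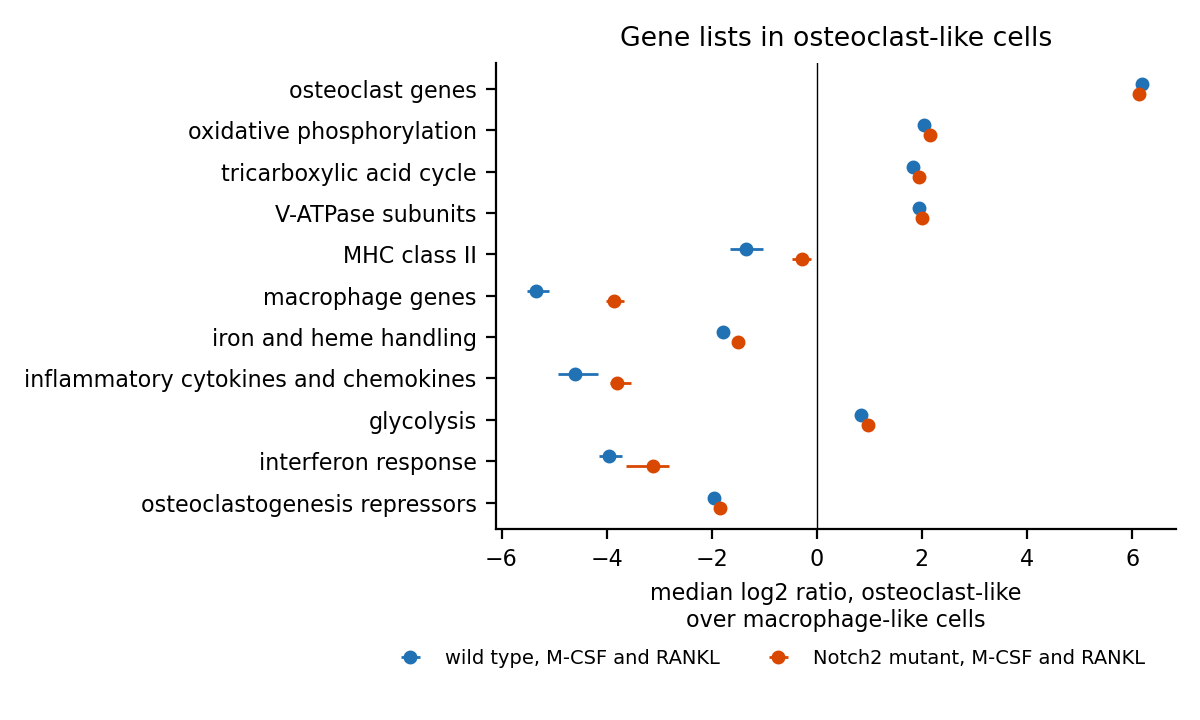
Median log2 ratio of 11 gene lists, osteoclast-like over macrophage-like cells of the same library, for the wild type and mutant RANKL libraries, with bars for counting intervals. Oxidative phosphorylation lies at 2.04 and 2.16 and macrophage genes at -5.34 and -3.86.

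Within osteoclast-like cells, the osteoclast genes stood at nearly equal levels in the mutant and the wild type, with a median log2 ratio of -0.071 (-0.11 to -0.022) over 25 genes. The cluster was named by such genes, which may in part fix their levels within it. Acp5 was at 12724 against 12827 CPM and Ctsk at 12425 against 12276 CPM. Oxidative phosphorylation differed by 0.046 (0.027 to 0.067) and glycolysis by 0.11 (0.019 to 0.16). Macrophage genes were higher in the mutant osteoclast-like cells, with a median of 1.45 (1.14 to 1.57) over 18 genes, as were MHC class II genes at 1.32 (1.01 to 1.74). The macrophage median was 0.918 with all barcodes and 0.965 without the 15 mutant and 9 wild type cells with the highest share of these transcripts. The 15 and 9 cells with the most such UMIs held 31.1% and 19.6% of them. The median share of macrophage genes in a cell's UMIs was 0.410% in mutant and 0.350% in wild type cells, and doublet removal did not work in the mutant library. Pooled over all osteoclast-like cells, these genes gave 0.482% of mutant and 0.384% of wild type UMIs, a narrower gap than the median over genes. Of 5677 genes, 82 were at least 2-fold higher in the mutant and 6 at least 2-fold lower. With each cell weighted equally the counts were 48 and 17, and with all barcodes 34 and 2. The highest ratios were those of Tgfbi, an extracellular matrix protein (3.59), the chemokine receptor Ccr2 (2.91), the coagulation factor F13a1 (2.79), H2-Aa (2.36) and Cybb, a subunit of the phagocyte oxidase (2.33), with 51.9%, 66.9%, 73.4%, 85.3% and 52.2% of their mutant UMIs in 5 cells. The 6 lower genes were Rpl39l (-3.67), S100a9 (-1.96), Nt5dc3 (-1.20), Arhgef28 (-1.07), Egfr (-1.04) and S100a8 (-1.03). In the wild type, 1 cell held 100% of the Rpl39l, 97.0% of the S100a9 and 95.9% of the S100a8 UMIs.

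The share of cells with an Atp6v0d2 UMI was compared at 3000 UMIs per cell. It was 5.70% (4.94 to 6.53) in wild type and 5.86% (4.96 to 6.87) in mutant cells with M-CSF, and 5.83% (5.07 to 6.68) and 7.77% (6.95 to 8.64) with RANKL. Thinning left out 519, 250, 602 and 1780 cells, 13.3%, 9.36%, 15.1% and 30.8% of those kept, which takes cells of low depth from the denominator most in the mutant RANKL library, and the unthinned shares were 12.4%, 11%, 10.2% and 11.1%, in the order wild type M-CSF, mutant M-CSF, wild type RANKL and mutant RANKL. In osteoclast-like cells the thinned share was 98.9% in wild type and 97.4% in mutant cells. In macrophage-like cells it was 7.02% and 7.09% with M-CSF and 3.22% and 3.81% with RANKL. Neutrophil-like cells, which should lack the transcript, gave 0.479%, 1.09%, 1.07% and 1.93% in the 4 libraries, at median depths of 6419, 3654, 4964 and 6072 UMIs against 13253, 8211, 9715 and 9662 in macrophage-like cells. The share is not ordered as the summed level is: in wild type cells Atp6v0d2 stood at 140 CPM with RANKL against 34.0 CPM with M-CSF, at nearly equal shares of cells. Most of its UMIs with RANKL came from the osteoclast-like cells, while the share of macrophage-like cells with a UMI was lower with RANKL, 3.22% against 7.02%.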

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

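Of the tests below, those on doublets by the median cell, on mitochondrial share, on filter loss of osteoclast genes and on the source of the osteoclast UMIs had predictions written before they were run. The tests of cell-filter loss on macrophage genes, of free RNA, of the tenth of cells richest in macrophage transcripts and of barcodes by mitochondrial share were chosen after the results were seen.

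Osteoclast genes were higher in the Notch2 mutant than in the wild type RANKL library. Within osteoclast-like cells their median log2 ratio was -0.071 (-0.115 to -0.021). These cells gave 9.23% of mutant and 6.43% of wild type UMIs (4.51% and 2.68% with the stricter filter, 11.11% and 8.88% with all barcodes). Both values go as predicted for more osteoclast RNA at an equal level within these cells. The first cannot decide it, because the cluster was grouped and named by these same genes, which may fix near-equal levels within it. The wild type library lost more osteoclast-like barcodes to the mitochondrial limit, 41.6% (33.9 to 49.6) against 28.8% (22.9 to 35.4). Among all barcodes this class joined a cluster of 319, led by Ctsk, with an unlike cluster of 57. The latter had a median of 8573 UMIs, and Calcr was the only osteoclast marker among its 10 leading genes. Its part in the loss was not separated, so the loss may not be one of osteoclasts alone. From 15% to 20% mitochondrial UMIs lay 32 wild type and 41 mutant ones, and above that 35 and 21. Among all barcodes above 30%, 31 wild type and 17 mutant ones were osteoclast-like, and Acp5 stood at only 383.3 and 309.8 CPM. The larger wild type loss thus lay above 20%, partly among barcodes in which Acp5 was low. With all barcodes the median was 0.236 (0.199 to 0.265), between the bounds of 0.1 and 0.25 set for a result of the filter and for no part of it, so uneven loss stays open. An effect of the genotype stays open too, untested with 1 library per group.

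Osteoclast-like cells had a higher share of mitochondrial UMIs than macrophage-like cells, 10.98% against 6.85% in wild type and 10.68% against 7.05% in mutant cells, at medians of 30212 against 9715 and 31311 against 9662 UMIs. Damaged cells that had lost cytoplasmic RNA stay open. Nuclear genes of oxidative phosphorylation were higher in osteoclast-like cells, the lower of the median log2 ratios being 2.036 (2.01 to 2.078), above the bound of 0.5 set beforehand for no damage. That bound was wrong, because a ratio between cell types also holds their identity: among all barcodes, set against kept macrophage-like cells without mitochondrial UMIs in the totals, macrophage-like ones with 15% to 20% mitochondrial UMIs had medians of -1.139 in wild type and -0.806 in mutant cells against 0.061 and 0.065 below 10%, and a fall of that size would leave osteoclast-like cells above the bound. By mitochondrial share, osteoclast-like barcodes had medians of 2.075, 2.105 and 2.144 in wild type and 2.21, 2.214 and 2.268 in mutant cells below 10%, from 10% to 15% and from 15% to 20%, which goes against damage but excludes nothing, as intact and damaged cells were not known. Above 20% the medians were 0.203 and 1.348, and barcodes of the unlike cluster of 57 described above may lie among these. A higher mitochondrial content of osteoclasts stays open too, as transcripts do not measure it.

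Macrophage genes were higher in mutant than in wild type osteoclast-like cells. More free RNA in the mutant library stays open because its readings disagree: without the tenth of osteoclast-like cells richest in S100a8 and S100a9, abundant neutrophil transcripts of which 1 wild type cell held 96.6%, the lower of their log2 ratios was 1.011 (0.435 to 1.625). In macrophage-like cells, again leaving out the tenth of cells richest in them, their joint ratio was 0.791. The background of osteoclast genes in macrophage-like cells was higher in the mutant by 0.273, less than the 0.522 by which the share of UMIs from osteoclast-like cells was higher. This background is a median over 12 genes and depends on that choice. Macrophage-like cells may transcribe some of them, such as Nfatc1, at 6.69% and 7.26% of the osteoclast level in wild type and mutant. Over 7 of the genes the medians were 0.219% and 0.291%, a wider gap but still narrower than that of the UMI share. Also open are doublets, at 0.227 (-0.039 to 0.38) for the median share per cell and 0.965 (0.55 to 1.113) without the tenth of cells richest in macrophage transcripts, filter loss, at 0.918 (0.695 to 1.007) with all barcodes, and the genotype, which is untested.

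The remaining results were picked out because the genotype ratio had opposite signs with M-CSF and with RANKL, differences that were not tested. For Csmd1 the log2 ratios were 1.47 with M-CSF and -1.98 with RANKL, with at least 98.4% of its UMIs in 5 cells or fewer of each library. For Hist1h2ap they were -1.17 and 1.62. For Igkc they were 0.58, from 54 mutant and 80 wild type UMIs, and -2.35. For Mpo they were -1.07 and 0.41. For Ppbp they were 1.56, from 24 mutant and 18 wild type UMIs, and -3.01. For Prg2 they were -7.29 and 3.95, the first computed with 0 UMIs set to 3 and the second with 95.8% of mutant UMIs in 5 cells. For oxidative phosphorylation the medians were -0.047 and 0.109, and for the dissociation and heat shock response 0.134 and -0.075. A signal also lay in barcodes that the filter removed: those with 15% to 20% mitochondrial UMIs held Acp5 at 6661.5 CPM in the wild type and 6930.4 CPM in the mutant RANKL library, against 2.95 and 8.64 CPM with M-CSF.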

How the results depend on the processing

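A count of genes is taken as kept if within 1.5 times the reported count, and a median, ratio or share if inside the counting interval of the reported value. Of the main results, 105 values were kept in this sense under the alternatives chosen at the outset and 61 under those added after seeing the data. Another 57 and 17 moved. Some kept values could not move: leaving out dividing cells or the low-UMI clusters takes away no osteoclast-like cell, so counts within these cells stayed the same. A reversal of sign was counted only for medians and ratios whose reported interval leaves out 0, so counts and shares could not reverse. Among the main results 0 osteoclast medians reversed. Among other values 207 and 59 were kept, 177 and 44 moved and 8 and 5 reversed. Of 16 shares per class under the other clusterings, 0 moved for osteoclast-like, macrophage-like and dendritic-like cells, 1 for monocyte-like, 14 for dividing and 12 for neutrophil-like cells. The osteoclast-like shares include those of the M-CSF libraries, which held 0 such cells in the main clustering. The clause that leaves low-UMI clusters unnamed applied in all these clusterings. No analysis paired by replicate was made, since the groups share only replicate number 1 and no result comes from a test. An additive fit of genotype and treatment over the 4 libraries, which would leave 1 residual degree of freedom, was not made. The osteoclast median for genotype lay between 0.116 and 0.465 with RANKL and between 0.022 and 0.074 with M-CSF. Unless a reason is given, the cause was not tested.

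With the stricter filter, which removes many osteoclast-like cells, 51 genes were at least 2-fold higher with RANKL in wild type and 74 in mutant cells, and the osteoclast medians were 1.965 and 2.193, with 0.465 for genotype with RANKL. With all barcodes the medians were 3.876, 3.489 and 0.236, and with up to 30% mitochondrial UMIs 3.868, 3.483 and 0.243. With each cell weighted equally, 12 genes were lower with RANKL in wild type, 66 higher and 17 lower in mutant cells, and 1 lower in the mutant with RANKL, and the osteoclast medians were 1.961, 1.854 and 0.129. Without osteoclast-like cells, a removal that takes out the cells named by these genes, 40 genes were higher and 14 lower with RANKL in wild type and 47 higher in mutant cells, and the medians were 0.044, 0.101 and 0.122. With cluster 12 left out too, 40 were higher and 14 lower in wild type and 46 higher in mutant cells, and the medians were 0.013, 0.087 and 0.116. With other cell types left out, 1 gene was lower in the mutant with M-CSF and 0 with RANKL, and the mutant's osteoclast median was 3.927. Without dividing cells the wild type median was 3.407. With list members of at least 20 CPM the medians were 2.047 and 2.443.

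With at least 50 CPM, which enters fewer genes, 39 were higher with RANKL in wild type, 62 higher and 21 lower in mutant cells, and 1 lower in the mutant with RANKL. With no CPM minimum, which enters sparsely counted genes, 1159 were higher and 325 lower with RANKL in wild type, 1261 and 359 in mutant cells, and the mutant had 309 higher and 481 lower with M-CSF and 352 and 450 with RANKL. Within osteoclast-like cells the genes higher and lower in the mutant numbered 34 and 2 with all barcodes, 137 and 36 with the stricter filter, 48 and 17 with equal cell weights, 28 and 2 with up to 30% mitochondrial UMIs, 22 and 2 at 50 CPM, and 675 and 210 with no minimum.

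Atp6v0d2 shares depend on depth by construction. In wild type M-CSF, mutant M-CSF, wild type RANKL and mutant RANKL libraries they were 3.01%, 3.66%, 4.2% and 5.65% at 1500 UMIs, 7.65%, 8.39%, 7.91% and 9.76% at 5000 UMIs, and 12.4%, 11%, 10.2% and 11.1% unthinned. With all barcodes the RANKL libraries gave 7.295% and 8.82%.

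Reversals of sign were as follows. With TMM factors, RANKL and AP-1 signalling (-0.021) and heat shock (-0.004) reversed for RANKL in wild type, and ribosomal proteins (0.009) for genotype with M-CSF. With equal cell weights, mitochondrially encoded genes (-0.179) and heat shock (0.031) reversed for RANKL in mutant cells, the interferon response (0.104) and Notch2 (0.029) for RANKL in wild type, and Ppbp (0.443) in the difference of responses. Without osteoclast-like cells, the tricarboxylic acid cycle (-0.002) reversed for genotype with RANKL, the interferon response (0.030) for RANKL in wild type and heat shock (0.058) for RANKL in mutant cells. With cluster 12 left out too, computed for 4 lists only, the tricarboxylic acid cycle (-0.015) and oxidative phosphorylation (-0.005) reversed for genotype with RANKL.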

Other observations

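Macrophage-like cells differed with RANKL too, examined by cell class after the whole-library values were seen. Of 6122 genes in wild type macrophage-like cells, 81 were at least 2-fold higher and 28 lower with RANKL; of 6103 in mutant cells, 107 and 28. These counts include free RNA from osteoclast-like cells, a class found in the RANKL libraries only: Acp5 and Ctsk stood at 56.8 and 35.2 CPM in wild type macrophage-like cells and at 36.5 and 38.6 CPM in neutrophil-like cells of the same library. With the osteoclast-like profile subtracted at the level of these genes in neutrophil-like cells, 0.299% in wild type and 0.301% in mutant cells, 78 and 105 of the higher genes remained, and at the level that removes all Acp5, 0.443% and 0.593%, 77 and 104. RNA from other cell types was not subtracted. Mmp9 was higher by log2 ratios of 5.10 in wild type and 4.97 in mutant cells, from 3.31 to 113 CPM and from 4.02 to 126 CPM, and by 4.537 and 4.196 after the larger subtraction. Cd55, a membrane inhibitor of complement, was higher by 4.99 and 5.36, and the membrane proteins Tmem176a by 3.45 and 3.22 and Tmem176b by 3.34 and 3.25. Vcam1, an adhesion molecule, was higher by 3.14 in wild type and 2.95 in mutant cells, and complement C3 by 2.63 and 2.51. The 5 higher genes named here other than Mmp9 lay at or below 7.14 CPM in wild type and 18.7 CPM in mutant osteoclast-like cells. In wild type neutrophil-like cells with RANKL, C3 stood at 512.9 and Vcam1 at 44.8 CPM, above their levels of 128.6 and 27.7 CPM in macrophage-like cells. In the mutant, C3 stood at 442.3 CPM in neutrophil-like and 139.1 CPM in macrophage-like cells, and Vcam1 at 39.98 and 40.04 CPM. Cd5l was lower by -2.56 and -2.66, Il1a, interleukin 1 alpha, by -1.90 and -2.11 and Ccl6 by -1.58 and -1.80. The osteoclast list had medians of only 0.072 and 0.14 in these cells, or -0.15 and -0.028 after the larger subtraction. That fall is in part built in. With M-CSF, where no osteoclast-like cells were found, macrophage-like cells held Acp5 at 11.1 and 14.7 CPM, and the larger subtraction removes such transcripts too. The smaller one also removed all Ctsk. The subtracted medians thus do not show that osteoclast genes were unchanged or lower. Oxidative phosphorylation stood at 0.14 and 0.12, or 0.10 and 0.071 after the larger subtraction. Inflammatory cytokines and chemokines stood at -0.25 and -0.40. Between genotypes, 0 of 5937 genes in macrophage-like cells were at least 2-fold apart with M-CSF, and 2 higher and 0 lower of 6090 with RANKL.

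MHC class II genes had the following genotype ratios by cell class, whose differences between classes were not tested. In macrophage-like cells the mutant's median was -0.90 (-1.03 to -0.66) with M-CSF and 0.39 (0.30 to 0.49) with RANKL, over 6 genes. In dendritic-like cells it was 0.16 (0.088 to 0.20) and 0.32 (0.21 to 0.41), over 10 genes. In monocyte-like cells it was 0.51 (0.18 to 0.63) and 0.096 (-0.16 to 0.26).

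As a reading of free RNA, the level of 12 osteoclast genes in other classes was taken as a percentage of that in osteoclast-like cells. The median over the 12 genes was 0.365% in wild type and 0.441% in mutant macrophage-like cells, and over 7 of them, picked after their values were seen, 0.219% and 0.291%. In neutrophil-like cells the 12 genes had medians of 0.290% and 0.321%. Neutrophil-like cells, which make their own Mmp9, held that gene at 9.52% and 9.77% of the osteoclast level.

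Checks were also computed on cluster 2, the unnamed cluster of low UMI counts, and are given as values only. The 13 neutrophil genes had median log2 ratios against the library sum of -4.22, -3.46, -4.78 and -3.85 in the wild type M-CSF, mutant M-CSF, wild type RANKL and mutant RANKL libraries. Malat1, a nuclear RNA, had log2 ratios over macrophage-like cells of -0.753, -0.805, -0.961 and -0.924.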
